A study of Mus musculus with 6 samples.

How the data were processed

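The 6 libraries came from mouse primary pulmonary fibroblasts, 3 labelled quiescent and 3 labelled senescent after Nutlin 3a, an inhibitor of the Mdm2 and p53 interaction. Per the labels' protocols, cells grew in medium with 10% serum at 5% oxygen. The labels describe the induction as 16 hours of RO3306, a Cdk1 inhibitor, then 48 hours of Nutlin 3a, then the Plk1 inhibitor BI-2536 at 100 nM against dividing cells, over 12 days in total. The same text stands on the quiescent samples, and how those cells were made quiescent is not given in the sources used here. Per the labels' protocols, total RNA was depleted of ribosomal RNA, libraries were made with a directional kit, and paired reads of 100 bp were sequenced. Replicates are separate samples in the labels, which do not say whether they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

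The authors deposited raw counts per gene symbol and raw counts per RepeatMasker repeat name, both as whole numbers that differ in total between libraries. The build mm10 and the tools edgeR 3.32.1 and limma 3.46.0 are named in the submitters' processing notes, without a stated role. The aligner, the counting tool, the use of strand and the handling of reads with several positions are not given in the sources used here. Counts of genes with near-identical copies (histones, Ifit3 and Ifit3b, ribosomal proteins with their pseudogenes, Gapdh, the granzyme and Mcpt cluster) and of overlapping or antisense genes are therefore uncertain. Repeat names share reads more widely still. Gene positions were taken from the GENCODE M21 annotation, whose assembly GRCm38 is the one mm10 names; 24321 of 25239 symbols matched it.

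Gene totals ran from 93736593 to 109706025 counts per library. The row Rn45s, the 45S ribosomal RNA precursor, held 73.2% to 75.5% of them, and with Lars2 and Mir6236 the share was 79.8% to 82.8%. These rows are called the ribosomal rows here, although Lars2 is not itself a ribosomal RNA gene. All other genes summed to 18219831 to 21386546 counts. Repeat totals ran from 244983845 to 291065749, of which 2 ribosomal RNA names held 97.5% to 98.0%, leaving 5860605 to 7247914. The repeat totals exceed the gene totals. Levels are given as CPM, the usual normalised count, computed on the TMM-adjusted gene total with ribosomal rows included, so they look low. With PCR reads and no molecular identifiers, depth covers counting error only.

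Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group with a minimum count of 10, TMM factors, a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. Standard errors of log2 fold changes are the log2 fold change divided by the square root of F. Repeat names went through the same test with the effective library sizes of the gene table. Gene lists (34) and repeat groups were fixed before the data were examined, as were the tests and most alternatives. Lists with at least 3 tested genes were also tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry; adjustment was over the 32 lists tested, and separately over the 9 lists added after the data were seen. Repeat groups were compared by the log2 ratio of summed counts, the 2 ribosomal RNA names left out, with an exact two-sided permutation test whose smallest p in this design is 0.1.

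Named genes followed a fixed rule: 10 markers; the 10 highest and 10 lowest log2 fold changes among genes that passed with a mean log2 CPM of at least 2; up to 2 risen and 2 fallen genes per list at a mean log2 level of at least 0; and 5 repeat names in each direction with 7 fixed ones. Symbols of unnamed or predicted genes (Gm numbers, Rik, LOC and accession-style names) were left out of the 10 highest and 10 lowest. Simple repeats were left out of the 5 repeat names in each direction. Other genes named in the text were chosen after their values were seen. Alternatives were DESeq2 1.42.0, limma-voom, other filters, thresholds and scalings, the replicate number as a block, and each library left out in turn. After the data were seen, scaling without the ribosomal rows, group sums without the most abundant name and group sums without names of other families were added.

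The test was tried on simulated counts for this comparison, with 200 changed rows per table. The changed rows were drawn above a minimum mean count and divided evenly between increases and decreases. All rows shared the common dispersion of their table, and no simulated library stood apart. The shares below hold for those settings and may differ in the real data, where more rows changed. Over 13974 genes it recovered 56.0% of the 50 genes changed 1.25-fold, 90.0% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold, with 9 false calls among 181. Over 1275 repeat names the shares were 28.0%, 78.0%, 98.0% and 100%, with 9 false calls among 161. No pair of libraries matched within sampling noise: the chi-square per degree of freedom over genes was 2.26 to 4.09 between quiescent libraries 3.90 between senescent replicates 1 and 2, and 15.6 and 19.9 between these and senescent replicate 3, which stood apart. Over repeat names senescent replicate 2 stood apart, at 50.4 and 58.9 from the others, which differed by 15.0, and quiescent replicate 3 likewise, at 28.2 and 42.7 against 8.87.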

Results

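The comparison asked which genes and transposable elements differed between quiescent and Nutlin 3a-induced senescent lung fibroblasts. Expression was measured by ribosomal RNA-depleted sequencing in 3 quiescent and 3 senescent libraries, with 93736593 to 109706025 counts per library in the gene table. Of these, 18219831 to 21386546 lay outside Rn45s, Lars2 and Mir6236, the 3 rows treated here as ribosomal.

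Of the fixed gene lists, all 40 mitosis genes, all 24 cholesterol synthesis genes and 37 of 43 interferon-stimulated genes were lower in senescent libraries, and 28 of 37 secretory phenotype genes were higher. Camera called these lists at a preset correlation, and no fixed list with an estimated correlation (lowest adjusted p = 0.266). Fry gave them adjusted p = 1.9e-05, 4.3e-06, 6.3e-04 and 1.4e-04 in that order. It also called MHC class I antigen presentation (fry adjusted p = 0.0071), which camera did not call. Fry asks only whether the listed genes changed, not whether they changed more than other genes, and most genes changed here. Il11, a cytokine of the interleukin 6 family, rose from 4.32 ± 0.303 to 762 ± 207 CPM (SD, n = 3 per group), a log2 fold change of 7.46 with a standard error of 0.24. Mmp13, a collagenase, rose from 2.79 ± 0.259 to 318 ± 88.0 (log2 fold change 6.83, standard error 0.25). Senescent replicate 3, which stood apart from the other senescent libraries, held the most of both (102870 Il11 counts against 61906 and 59532). Mki67, a marker of dividing cells, fell from 52.6 ± 2.13 to 10.4 ± 1.34 (log2 fold change -2.33, standard error 0.08). In edgeR's quasi-likelihood test, 5158 of 14065 tested genes were higher and 5316 lower in senescent libraries at an adjusted p under 0.05, which is 74.5% of the genes. Point estimates beyond 2-fold were found for 1544 higher and 2010 lower genes. Scaling by library totals without TMM moved the median log2 fold change of all genes from -0.02 to -0.32 and the split to 2952 higher and 7435 lower, and upper quartile scaling moved the median to -0.12. Those totals are mostly ribosomal rows (79.8% to 82.8%). With the ribosomal rows left out and TMM kept, the median was -0.02, with 5148 higher and 5315 lower. Against a 2-fold threshold tested directly (glmTreat), 1154 genes were higher and 1309 lower.

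The p53 and cell cycle arrest markers fixed in advance went in different directions. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 29.9 ± 0.901 to 65.8 ± 5.25 CPM (log2 fold change 1.14, standard error 0.06, adjusted p = 1.3e-08 in edgeR). Mdm2, the ubiquitin ligase that Nutlin 3a separates from p53 (chromosome 10, 117688875 to 117710758), rose by 0.95 on the log2 scale, Trp53 by 0.63 and Gdf15 by 1.08. Il6, a secreted cytokine (chromosome 5, 30013114 to 30019981), rose by 3.53 on the log2 scale (standard error 0.10). Cdkn2a, whose locus encodes p16 and p19Arf (chromosome 4, 89274471 to 89294653), fell from 1.01 ± 0.0468 to 0.535 ± 0.162 (log2 fold change -0.93, adjusted p = 9.9e-04 in edgeR). Its neighbour Cdkn2b had a log2 fold change of -0.41, the nuclear lamina gene Lmnb1 of -0.49 and Glb1, which encodes lysosomal beta-galactosidase, of -0.34, and each of these passed the test as lower. For all 123 named genes the 3 senescent libraries lay beyond the 3 quiescent ones, where chance alone gives 10% per gene; all but the fixed markers were chosen for passing.

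**Figure D1:**
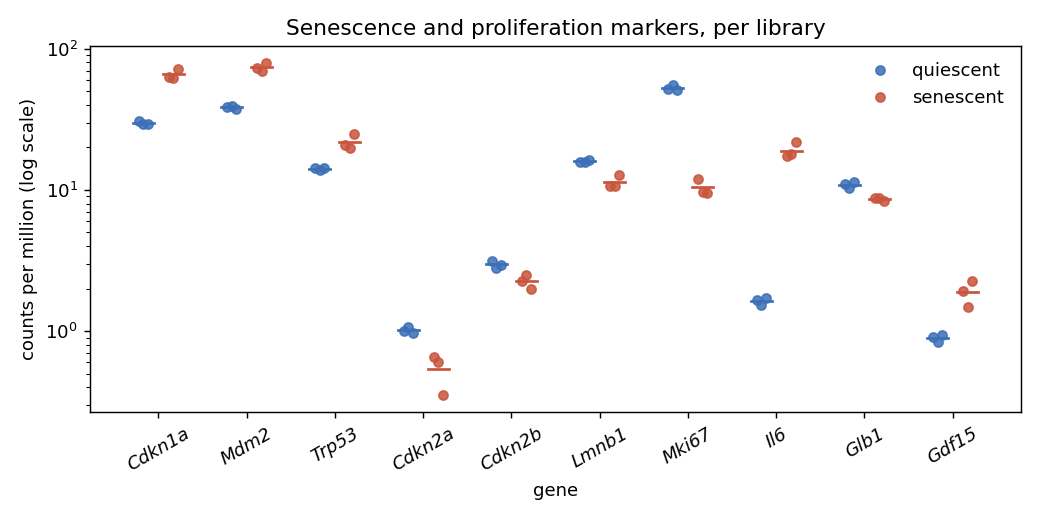
CPM (log axis) of the 10 fixed markers in each of the 3 quiescent and 3 senescent libraries; each point is a library and each bar the group mean. Cdkn1a, Mdm2, Trp53, Il6 and Gdf15 lie higher in every senescent library, and the other 5 genes lie lower.

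Among 35 tested p53 target genes, 13 rose and 13 fell, and the counts were 13 and 13 adjusted over the list alone. These shares are near those over all tested genes, of which 5158 of 14065 were higher and 5316 lower. Plk2, a stress-responsive kinase gene, rose by 2.48 on the log2 scale and Pmaip1, which encodes the apoptosis factor Noxa, by 1.52, whereas Sesn1 (-1.90) and Dcxr (-1.53) fell. The median log2 fold change was -0.04 and the mean 0.04, opposite in sign, and camera gave an adjusted p of 0.895 in the downward direction (adjusted p = 0.949 with an estimated correlation). Under library totals 9 rose and 20 fell. In all, camera called 20 of the 32 tested lists at the preset correlation.

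Cell division genes fell almost throughout. The described induction included BI-2536 against dividing cells, and how the other cells were made quiescent is not given. A loss of dividing cells to the drug, or dividing cells left in the quiescent cultures, therefore cannot be told apart from senescence here. All 40 genes of the G2/M and mitosis list fell, also adjusted over the list alone, with a median log2 fold change of -2.05 (camera adjusted p = 1.9e-14, and adjusted p = 0.266 with an estimated correlation). Nusap1, a spindle protein gene, fell by 2.93 on the log2 scale and Cenpf, a kinetochore protein gene, by 2.89. Of 38 G1/S and DNA replication genes, 32 fell and 0 rose, the same counts adjusted over the list alone, with a median of -0.60 (camera adjusted p = 3.2e-06, and adjusted p = 0.279 with an estimated correlation). Tk1 and Lig1, for thymidine kinase and a DNA ligase, fell by 1.57 and 1.38. Of 23 homologous recombination and Fanconi genes, 20 fell (21 fell and 1 rose adjusted over the list alone), among them Fancd2 (-1.81) and Eme1 (-1.58), with camera adjusted p = 2.8e-06 and adjusted p = 0.279 with an estimated correlation. Among 52 tested replication-dependent histone genes, 46 fell and 2 rose (47 and 3 adjusted over the list alone; camera adjusted p = 3.2e-10, and adjusted p = 0.266 with an estimated correlation). H2bc18 fell by 2.13 and H2bc4 rose by 0.69, and the increase of H1f2, 0.29, was lost under library totals (-0.0063, adjusted p = 0.94 in edgeR). All 10 nuclear genes reported to fall in senescence fell, also adjusted over the list alone, with Hmgb2 at -1.87 and Parp1 at -1.14 (camera adjusted p = 0.0012, and adjusted p = 0.266 with an estimated correlation).

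Of 37 genes of the senescence-associated secretory phenotype, 28 rose and 5 fell, the same adjusted over the list alone, with a median of 1.94 (camera adjusted p = 4.0e-06, and adjusted p = 0.380 with an estimated correlation). The median difference of these genes between senescent replicate 3 and the mean of the other senescent libraries was 0.39 on the log2 scale, and without that library 28 rose and 5 fell. Beside Il11, the neutrophil chemokine gene Cxcl3 rose by 7.34 (standard error 0.65) from 4, 1 and 2 quiescent counts, and by 7.95 without quiescent replicate 1, while Igfbp4 (-1.68) and Il33 (-1.56) fell. Of 29 matrix proteases and inhibitors, 17 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.266 with an estimated correlation). Serpinb2, a plasminogen activator inhibitor gene, rose by 6.97 (7.72 without quiescent replicate 2) and the aggrecanase gene Adamts5 fell by 3.84. The other genes among the 10 highest were Kcnk10 (7.46), Cxcl2 (7.33, standard error 0.82, and 6.68 without senescent replicate 3), Gzme (7.07), Crct1 (6.82), Sema7a (6.66), Mcpt8 (6.64) and Il1rl1 (6.49). Il1rl1, which encodes the interleukin 33 receptor, reached 599 ± 151 CPM from 6.65 ± 1.12.

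Actin genes of fibroblasts mostly rose, and collagen and matrix genes had no shared direction. Of 23 myofibroblast and actin cytoskeleton genes, 22 rose and none fell, also adjusted over the list alone, with a median of 1.09 (camera adjusted p = 9.2e-07, and adjusted p = 0.394 with an estimated correlation). Their median difference between senescent replicate 3 and the other senescent libraries was -0.33. Tagln, a smooth muscle actin-binding protein gene, rose from 77.9 ± 8.99 to 487 ± 49.9 CPM and Cnn1 rose by 3.29 on the log2 scale. Of 40 collagen and matrix genes, 17 rose and 16 fell, also adjusted over the list alone, with a median of -0.04 and a mean of 0.11, opposite in sign (camera adjusted p = 0.894 upward, and adjusted p = 0.957 with an estimated correlation). Tnc, the gene of tenascin C, rose from 159 ± 8.81 to 1739 ± 177 CPM, while Eln, the gene of elastin, fell from 253 ± 29.6 to 18.8 ± 5.97. Of 25 lung fibroblast identity genes, 16 fell and 5 rose, also adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.435 with an estimated correlation), among them Limch1 (-4.15), G0s2 (-3.06), Thy1 (2.72) and Npnt (1.92). Of 29 complement and quiescence-associated genes, 22 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 1.7e-04, and adjusted p = 0.279 with an estimated correlation). Gas1, a growth arrest gene, fell by 4.29, and Fabp4 rose by 1.38. Beside Gas1 and Limch1, the 10 lowest genes were Adamts15 (-5.59), Bmp3 (-5.46), Scara5 (-5.03), Cdo1 (-4.39), Abca8a (-4.38), Sfrp2 (-4.28), Adh1 (-4.17) and St8sia2 (-4.14).

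Interferon-stimulated genes were mostly lower. Of 43 tested, 37 fell and 2 rose, also adjusted over the list alone, with a median of -1.14 (camera adjusted p = 5.6e-07, and adjusted p = 0.394 with an estimated correlation). Their median difference between senescent replicate 3 and the other senescent libraries was -0.32. Ifit3 and Ifit3b, near-identical genes whose counts are uncertain because reads can be shared, had log2 fold changes of -2.83 and -2.84. Ifnb1 had 1 count in a quiescent library and 0 in the other 5. Of 18 nucleic acid sensing genes, 13 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.266 with an estimated correlation). Samhd1, a dNTP hydrolase gene, fell by 2.02 and Ifi204 by 2.37. The increases of Adar (0.27) and Rnaseh2a (0.21) were lost under library totals (-0.024 and -0.086, adjusted p = 0.82 and 0.41 in edgeR). Rnaseh2a did not pass without quiescent replicate 1 or 2 or senescent replicate 2 (adjusted p 0.073 to 0.089 in edgeR), and the 2 risen interferon-stimulated genes became 0 or 1 without quiescent replicate 1 or 2 or senescent replicate 1 or 2. Of 18 genes of antigen presentation by MHC class I, 10 fell and 5 rose, also adjusted over the list alone (camera adjusted p = 0.460, and adjusted p = 0.649 with an estimated correlation). B2m (0.67) and H2-T23 (0.63) rose, and the peptide transporter gene Tap1 (-1.28) and the immunoproteasome gene Psmb8 (-1.19) fell. Of 34 transposon silencing genes, 23 fell and 4 rose, also adjusted over the list alone, with Apobec3 at -1.53 and Kdm1a at 0.52 (camera adjusted p = 0.0017, and adjusted p = 0.266 with an estimated correlation).

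All 24 cholesterol synthesis genes fell, also adjusted over the list alone, with a median of -2.04 (camera adjusted p = 4.7e-11, and adjusted p = 0.266 with an estimated correlation). Tm7sf2 fell by 3.53 and Mvk, the gene of mevalonate kinase, by 2.87 on the log2 scale. Of 27 glycolysis and hypoxia genes, 23 rose and 2 fell, also adjusted over the list alone, with Egln3 at 3.96 and Vegfa, an angiogenic growth factor gene, at 3.24 (camera adjusted p = 6.7e-08, and adjusted p = 0.266 with an estimated correlation). Of 26 ATF4 and unfolded protein response genes, 19 rose and 2 fell, also adjusted over the list alone, with the serine synthesis gene Phgdh at 2.99 and Xbp1 at -0.21 (camera adjusted p = 8.4e-04, and adjusted p = 0.279 with an estimated correlation). Of 24 NRF2 antioxidant genes, 19 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 6.1e-04, and adjusted p = 0.266 with an estimated correlation). Hmox1, the heme oxygenase gene, rose by 3.10, Slc7a11 rose by 3.00 and Gstm1 fell by 2.27. Of 20 immediate early genes, 17 rose and 3 fell, also adjusted over the list alone, with Fosl1 at 3.89, Ier3 at 3.59 and Klf4 at -1.20 (camera adjusted p = 1.4e-04, and adjusted p = 0.404 with an estimated correlation), and a median difference between senescent replicate 3 and the other senescent libraries of 0.41. Of 40 lysosome and autophagy genes, 18 rose and 15 fell, not far from the shares over all tested genes. The counts were the same adjusted over the list alone (camera adjusted p = 0.547, and adjusted p = 0.785 with an estimated correlation). Sqstm1 rose by 1.40 and Scarb2 fell by 1.63. Of 76 cytosolic ribosomal protein genes, 29 rose and 8 fell (25 and 6 adjusted over the list alone; camera adjusted p = 0.069, and adjusted p = 0.564 with an estimated correlation). The median of the lysosome list, 0.09, became -0.21 under library totals and -0.01 under upper quartile scaling, and that of the ribosomal proteins, 0.10, became -0.20 under library totals, where 3 rose and 38 fell. Without any one of quiescent replicates 1, 2 or 3 or senescent replicate 1, 3 to 5 ribosomal protein genes fell. Camera called the ribosomal proteins as higher with RLE size factors (adjusted p = 0.048), without quiescent replicate 1 (adjusted p = 0.044) and without senescent replicate 1 (adjusted p = 0.033), over a range of 0.033 to 0.929 in all alternatives.

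**Figure D2:**
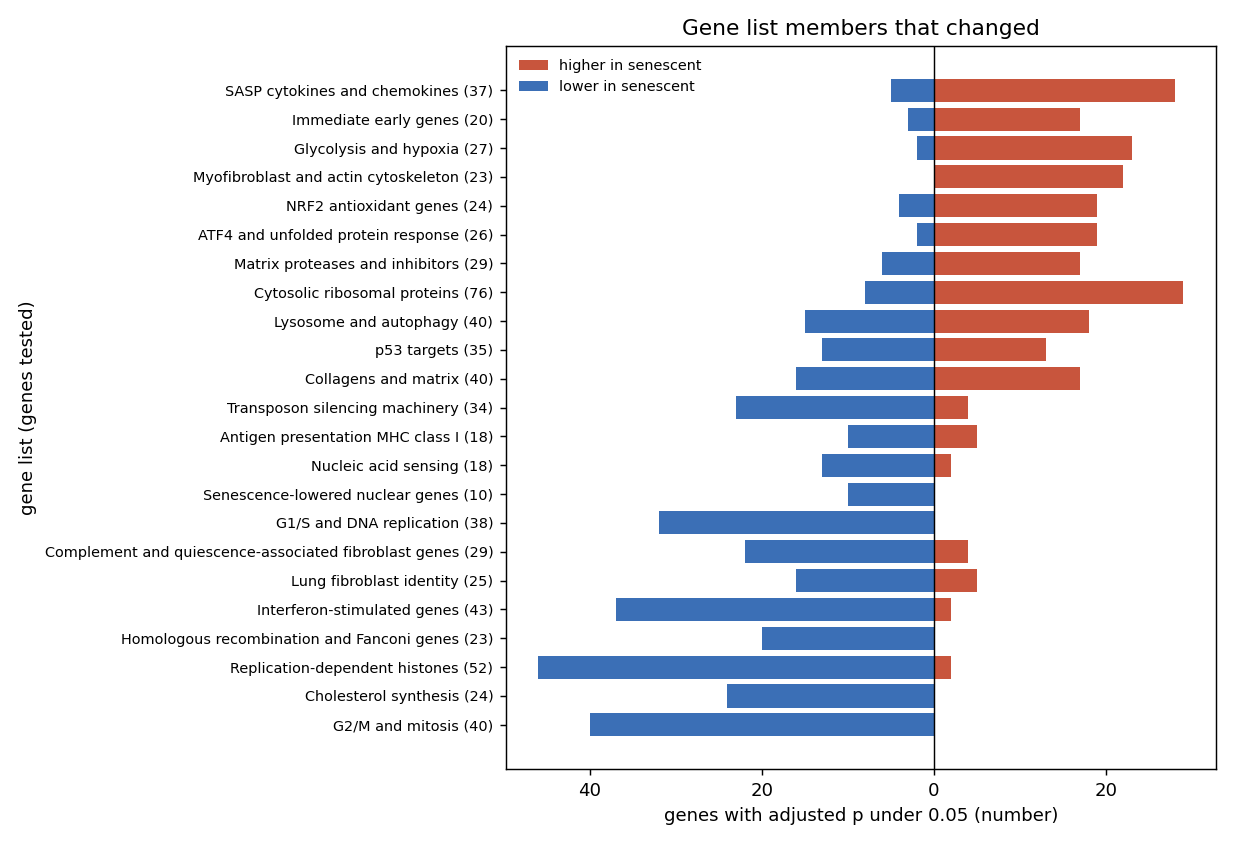
Number of genes in each pathway list with an adjusted p under 0.05, higher in senescent libraries to the right and lower to the left, with the number tested in brackets. All 40 mitosis genes and all 24 cholesterol synthesis genes lie on the lower side, and 28 of 37 secretory genes lie on the higher side.

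Of the cell type marker lists, camera called those of macrophages and of smooth muscle and pericytes at the preset correlation. Of 9 macrophage markers above the filter, 7 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.435 with an estimated correlation), with Lyz2 going from 0.779 ± 0.103 to 2.52 ± 0.624 CPM and Cd14 from 2.31 ± 0.110 to 6.88 ± 0.946. The camera call of this list was lost without senescent replicate 3 (adjusted p = 0.061), whose median difference from the other senescent libraries was 0.58. Of 14 smooth muscle and pericyte markers, 10 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.435 with an estimated correlation), with Cspg4 at 2.48 and Abcc9 at -0.90; Cnn1 is in this list and in the myofibroblast list. The same median difference was -0.50 for this list, -0.52 for skeletal muscle, -0.37 for mesothelial and 0.33 for endothelial markers. Endothelial markers gave 3 risen and 2 fallen of 10, with Tek at -2.67 and Flt1 at 2.16. Mesothelial markers gave 1 risen and 6 fallen of 11, with Rspo1 at -4.19, and epithelial markers 3 risen and 2 fallen of 6. Krt19 is in both lists and rose by 2.96. Adipocyte and lipofibroblast markers gave 3 risen and 7 fallen of 10, with Plin2 at 1.62 and Plin4 at -2.09; 5 or 6 rose without any one of quiescent replicates 1, 2 or 3 or senescent replicate 1. Chondrocyte and osteoblast markers gave 4 risen and 2 fallen of 8 (4 and 3 adjusted over the list alone), with Runx2 at 1.55 and Alpl at -0.92. Neural markers gave 2 risen and 4 fallen of 7, with Map2 at -2.84, and skeletal muscle markers 4 risen and 2 fallen of 7, with Acta1 at 5.05 and Myh1 at -2.62. For the endothelial, mesothelial, epithelial, adipocyte, neural and muscle lists the counts adjusted over the list alone were the same, and camera called neither these nor the chondrocyte list (adjusted p from 0.110 to 0.636), except the mesothelial list without senescent replicate 1 (adjusted p = 0.033). No lymphocyte marker passed the filter for testing, and the 13 mitochondrially encoded protein genes were not analysed here.

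Repeat-derived RNA moved apart by family when scaled by the gene table. MMVL30-int, the internal part of the VL30 retrotransposon, rose from 1164 ± 26.7 to 7358 ± 483 CPM (SD, n = 3 per group; log2 fold change 2.66, standard error 0.08, adjusted p = 2.3e-10 in edgeR). Its terminal repeats RLTR6_Mm and RLTR6C_Mm rose by 3.07 and 3.08, and RLTR6-int, a further internal name, rose by 1.12. In the same test, 763 of 1274 repeat names were lower in senescent libraries and 121 higher, with a median log2 fold change of -0.50. These counts weigh every name alike. Summed over all groups at this scaling, repeat RNA outside the 2 ribosomal RNA names was higher in senescent libraries. As a share of the repeat table's own totals it overlapped between the groups. The 2 ribosomal RNA names held 97.5% to 97.9% of those totals in quiescent and 97.5% to 98.0% in senescent libraries. Most repeat groups had lower sums. The groups with higher sums included MuLV and VL30 (1919 to 8591 CPM), small RNA repeats (5178 to 8728 CPM) and young L1Md names (16366 to 20634 CPM). The split of names moved with the scaling. With the repeat table's own totals and TMM factors, which centre the names, 361 were higher and 326 lower and the median was -0.01, with its own totals 53 were higher and 918 lower, and with gene totals without TMM 60 and 958. Leaving out simple and small RNA repeats gave 57 higher and 670 lower. Senescent replicate 2 stood apart over repeat names, with a median difference from the other senescent libraries of -0.28 on the log2 scale, and without it 153 names were higher and 738 lower.

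Of 117 tested LINE-1 names outside the young L1Md set, 104 fell and 1 rose, and their summed counts had a log2 ratio of -0.58 ± 0.11 (standard error). Of 119 names grouped by pattern as MaLR, which include MLT2 and MLTR names of other families, 96 fell and 6 rose, with a ratio of -0.60 ± 0.13 (72 of 90 fell and -0.61 without those), and of 7 B2, B3 and B4 names 6 fell, with -0.57 ± 0.14. B1 names had 13 of 15 fallen and a ratio of -0.31. The median difference between senescent replicate 2 and the other senescent libraries was -0.40 for these LINE-1 names, -0.35 for the MaLR group, -0.37 for B2, B3 and B4 and -0.28 for B1, and without that library the ratios were -0.48, -0.49, -0.44 and -0.21. With the repeat table's own TMM factors the ratios became -0.08 for these LINE-1 names (54 fell, 12 rose), -0.10 for the MaLR group (51 fell, 20 rose), -0.07 for B2, B3 and B4 (0 fell, 1 rose) and 0.20 for B1 (0 fell, 7 rose). The MuLV and VL30 group, which by its name pattern also holds RLTR11 to RLTR19 and RLTR41 to RLTR49, had a ratio of 2.16 ± 0.05, yet 52 of its 96 names fell and 6 rose (23 fell and 25 rose with the repeat table's own TMM factors). Without those names the ratio was 2.41, and 4 of 17 names rose and 4 fell. In the whole group MMVL30-int held 80.6% of its counts, and without it the ratio was 0.71. IAP names, an active family of endogenous retroviruses, had 4 risen and 9 fallen of 22 (8 risen and 2 fallen with own TMM factors, 0 and 13 with the repeat table's own totals, 1 and 14 with gene totals) and a ratio of 0.17, which became -0.12 under both unscaled totals, while their median log2 fold change was -0.44. IAPEz-int itself rose by 0.27 (adjusted p = 0.021 in edgeR), a call lost without any one of quiescent replicates 1, 2 or 3 or senescent replicate 1 (adjusted p 0.057 to 0.074). The call was also lost under the repeat table's own totals (-0.025) and gene totals (-0.027). Of 6 young L1Md names, 2 rose and 1 fell (4 and 1 with own TMM factors, 0 and 3 under both unscaled totals). Their summed counts went from 16366 to 20634 CPM, a ratio of 0.33 ± 0.08 (0.83 with own TMM factors, 0.030 under both unscaled totals). L1Md_F3 held 50.5% of the counts of this group and rose by 0.46 from 7877 CPM, and without it the ratio was 0.20. L1Md_F2 did not pass (0.17 from 7337 CPM, adjusted p = 0.085 in edgeR), and L1Md_A fell by 0.77 from 13.7 CPM. Other fixed names were MERVL-int at 0.37, GSAT_MM at 0.80, MMERVK10C-int at -0.59 and B2_Mm2 at -0.50, and each passed, while the fixed names L1MdA_I and L1MdTf_I were not analysed here. The call of MERVL-int was lost under both unscaled totals, and those of MMERVK10C-int and B2_Mm2 with the repeat table's own TMM factors. The other names with the largest changes, at levels under 2 CPM, were LTR9 (3.98) and ERVB4_3-I_MM-int (2.31), and downward MER4CL34 (-3.14), MamGypLTR2c (-2.77), MER125 (-2.70 from 5, 1 and 2 senescent counts, and -3.46 without senescent replicate 1), MER70-int (-2.11) and MamRep4096 (-2.01). Exact two-sided permutation tests of the group ratios gave 0.1, the smallest p of this design, for every group except simple repeats (0.7).

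**Figure D3:**
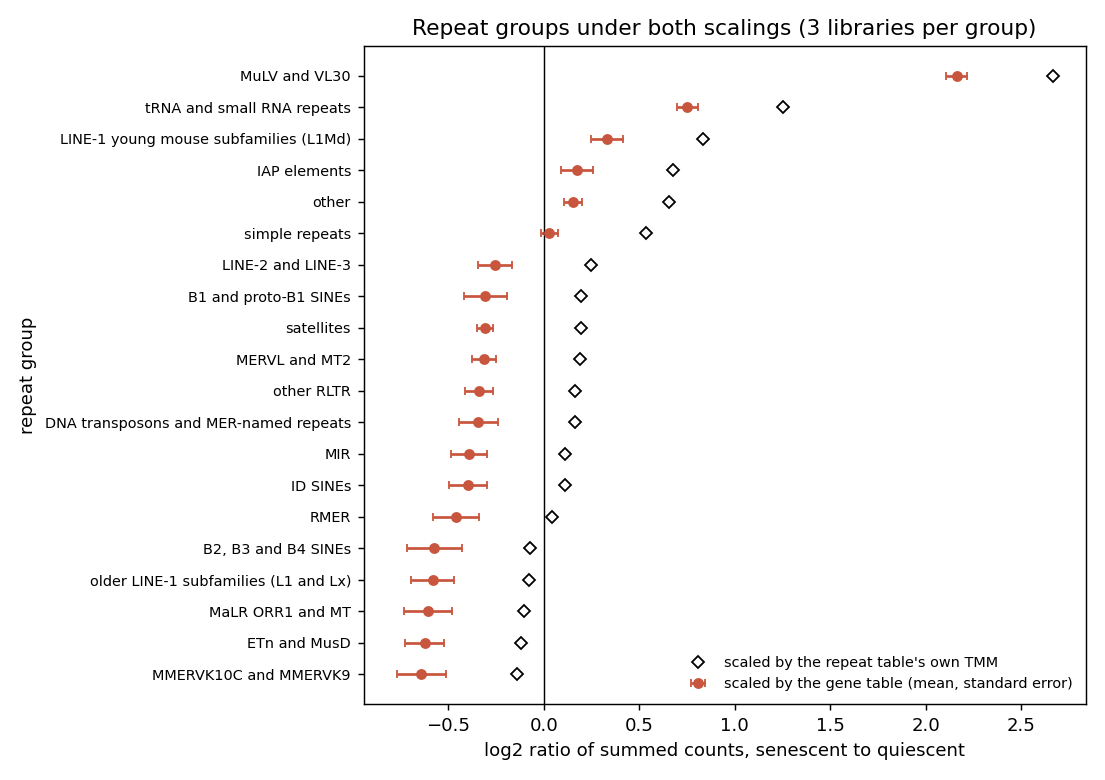
Log2 ratio of summed counts, senescent to quiescent, for each repeat group scaled by the gene table (filled points, standard error, 3 libraries per group) and by the repeat table's own TMM factors (open diamonds). MuLV and VL30 lies highest under both, and the B1 group, at -0.31 and 0.20, is among those that change sign.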

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

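Scaling without ribosomal rows and sums without the top name or names of other families were chosen after the data were seen. Every count of genes stayed within 1.5 times of 5158 higher and 5316 lower except under glmTreat (1154 and 1309) and library totals (2952 higher). Left-out libraries gave 4860 to 5331 higher and 4901 to 5416 lower, with fewer samples. Repeat counts, 121 higher and 763 lower, became 19 and 18 under glmTreat, 345 and 267 with DESeq2, 361 and 326 with the repeat table's own TMM (354 and 331 without its ribosomal rows), and 53 higher with its own totals, 60 with gene totals and 57 with transposable elements alone. DESeq2 used its own size factors. Left-out libraries gave 101 to 153 higher and 644 to 846 lower. Replicate numbers are shared by label only: same-number residuals correlated at 0.051, -0.010 and 0.058, and 3 of 6 libraries correlated best with their own number. With the replicate block, 5124 genes were higher and 5281 lower, and 114 and 756 repeat names; it ended no call of a named gene or repeat name. Of 2450 alternative values for 143 named genes and repeats, 2375 kept direction and call, 63 lost it (41 under glmTreat), 4 gained it and 8 changed sign; of 255 for 15 genes named later, 243 kept both and 12 lost the call. The sign changes were H1f2 (-0.0063), Adar (-0.024) and Rnaseh2a (-0.086) under library totals, B2_Mm2 (0.00073) with DESeq2, and IAPEz-int (-0.025 and -0.027) and L1Md_F2 (-0.13 and -0.13) under its table's own and the gene totals. Camera's direction turned for p53 targets and ribosomal proteins under library totals (adjusted p = 0.929 for each) and for collagens without senescent replicate 2 (left-out libraries gave 0.698 to 0.976). Camera called 19 to 22 lists with a library left out and 20 or 21 under other scalings, limma-voom and the block. Group ratios turned with own TMM for LINE-2 and LINE-3 (0.25), B1 (0.20), MIR (0.11), MERVL (0.19), other RLTR (0.17), satellites (0.19), DNA transposons (0.16), RMER (0.044) and ID (0.11). Under gene and own totals they turned for IAP (-0.12 and -0.12), simple repeats (-0.27 and -0.27) and other names (-0.15 and -0.15), for simple repeats also without senescent replicate 3 (left-out libraries gave -0.0043 to 0.068), and for small RNA repeats without 7SLRNA (-0.39). The cause was not tested. Depth was not varied in the simulation, where 28.0% of the smallest repeat changes were recovered, so its share in missed changes is unknown.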

Other observations

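Several gene groups outside the fixed lists moved; their lists, and the tests of the nuclear RNA share, the scaling of repeats, the 3 VL30 tests and the replicate spread, were chosen after values were seen. Of 13 prostaglandin genes, 10 rose and 3 fell: Ptgs2, the inducible cyclooxygenase gene, went from 11.9 to 946 CPM (log2 fold change 6.31, standard error 0.22, n = 3 per group, adjusted p = 1.9e-07 in edgeR), and the receptor gene Ptger4 fell by 0.76. Of 8 EGF-family ligand genes, 6 rose and 1 fell, with Ereg at 4.15 and Hbegf at 5.24, and of 14 MAPK feedback genes 12 rose and 2 fell, with Dusp5 at 4.84 and Spry1 at -1.84. Of 12 NF-kB feedback genes, 9 rose and 1 fell, with Tnfaip3 at 3.16 and a median difference of 0.50 between senescent replicate 3 and the other senescent libraries. The same difference was 0.27 for EGF ligands, 0.19 for MAPK feedback and 0.096 for prostaglandin genes. With an estimated correlation none of these 4 lists was called (adjusted p = 0.180 for prostaglandin genes, 0.343 for EGF ligands, 0.236 for MAPK feedback and 0.405 for NF-kB feedback).

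Lipid genes beyond cholesterol synthesis were lower too. Of 12 fatty acid synthesis genes, 11 fell and 1 rose, with Fads2 at -2.68 and Scd2 falling from 435 to 85.1 CPM, and of 10 LXR target genes 9 fell and 1 rose, with Nr1h3 at -2.43 and Abcg1 at 1.37 (adjusted p = 0.180 with an estimated correlation for both lists, which share Scd1, Scd2 and Srebf1). Of 355 tested genes named Zfp, 200 fell and 51 rose, with a median of -0.33 (camera adjusted p = 1.1e-04, and adjusted p = 0.0079 with an estimated correlation, each over the 9 lists chosen after values were seen). Of 8 genes of interferon receptors and their signalling, 5 fell and 2 rose, with Ifnar2 at -0.70 and Ifngr2 at 0.99 (adjusted p = 0.405 with an estimated correlation). Of 12 nuclear-retained RNAs, 7 fell and 3 rose, with Firre at -1.13 and Malat1 at -0.37, a call lost without any one library except senescent replicate 3 (adjusted p 0.068 to 0.096 in edgeR). The list had an adjusted p = 0.575 with an estimated correlation. The 7SLRNA name, for the RNA of the signal recognition particle, rose from 4244 to 8013 CPM and held 87.8% of the counts of small RNA repeats.

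Most repeat names that passed were lower in senescent libraries when scaled by the gene table, although repeat RNA summed over all groups was higher. Broadly lower expression of the genes whose introns hold repeats would lower an intron-weighted sum. Exon read density times intron length over 13049 genes had a log2 ratio of 0.14 (standard error 0.013). That sum did not fall, if unspliced reads follow exon density. It is weighted by abundance, whereas the pattern counts every name alike. Summed repeat RNA rose too at the gene table's scaling, so the ratio does not speak against this cause of lower names. The sum was also not weighted by repeat content, so it does not exclude lower expression of the genes that hold particular names. Scaling by the gene table stays open: TMM factors of the repeat table centre its names, so the 47.5% of called names that were lower with them decide nothing, and 94.5% were lower with its own totals, mostly ribosomal RNA. A lower share of unspliced and nuclear RNA, or a change in repeat transcription with senescence, which was not tested, stays open too. The 216 names of old families, themselves part of the pattern, had a median of -0.58 against -0.49 for the other 1058. Those 1058 include the older LINE-1 names and simple repeats, so the contrast is not of old against young names and decides nothing. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave 884 names, and the highest other gave 0 in edgeR, with DESeq2 and limma-voom also at 0 and 9 names at an unadjusted p under 0.05.

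The VL30 names rose against that trend. Reads shared with MuLV and MuRRS names would raise those as well, but MuLV-int, RLTR4_MM-int, RLTR4_Mm, MuRRS-int and MuRRS4-int had a median log2 fold change of -0.042 (range -0.41 to 0.19), and of at most 0.48 under the alternatives. The lowest value of MMVL30-int over the 5 scalings was 2.36, so scaling alone leaves the increase in place. RLTR6-int, an internal name left out of those 5, rose by 1.12 on the log2 scale, less than MMVL30-int, and reads shared between these 2 names stay open, as does a change with senescence, which was not tested.

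Most genes passed the test. The biological coefficient of variation was 0.0638, so replicates that vary less than separate cultures would may have added calls, and this cannot be told apart from uniform cultures because the labels name no cultures. Length bias would tie fold change to exonic length, but Spearman's rho across 13758 genes, which are not independent replicates, was -0.0075. Of the 10 splits, too few for a share under 0.05, 1, the real one, gave 10474 genes, and the highest other gave 0 in edgeR, DESeq2 and limma-voom, with 44 genes at an unadjusted p under 0.05.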
